A study of Drosophila melanogaster with 2 samples.

How the data were processed

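Chromatin immunoprecipitation followed by sequencing was run on whole wandering larvae of the last instar of a fly line whose transgene makes GATAd with green fluorescent protein at its C terminus. Per the labels, chromatin was sheared by sonication and precipitated with an antibody against the tag; another label field names GATAd as the antibody target. The 2 samples form 1 group, GATAd-GFP larvae, and are biological replicates 2 and 3 of separate larval samples. Control libraries are named in the labels and were not analysed here.

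The files are 8 peak lists, 4 on each of the builds dm6 and dm3. Per the file headers and the deposited file records, each build has candidates for replicate 2, candidates for replicate 3, candidates for both replicates pooled, and the optimal list that passed the IDR threshold. The candidate lists hold 30000 peaks each and include background by design. All candidate lists of a build were called against the same control, and the IDR list derives from the other 3. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The authors' signal is the deposited value of column 7 of each list, a peak caller's enrichment over the control whose scale is not stated. It was used to rank, describe or filter peaks within a list, to correlate the replicate lists across peaks, and in log2 ratios between the replicate lists, where single peaks are given relative to the median over peaks. The lists need not share a scale, which leaves the correlations unchanged if the scales differ by a factor. The deposited score of column 9, which the format reserves for a q-value, fell as the signal rose in the lists of replicate 2 and of the pool on dm6 (Spearman's rho -0.694 and -0.478) and rose with it in replicate 3 (0.9999). In the IDR list it rose with the signal as well (0.994). Columns 5 and 8 hold no information in any list. The read depth of each library is unknown, so no interval that needs it is given, and intervals on shares cover the counting of peaks only.

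Analyses used dm6, the newer build. Peak coordinates are 1-based and fit within the arms of the Release 6 reference sequence, to which dm6 corresponds, with 0 peaks past the end of an arm. Protein-coding genes and their transcripts came from Ensembl's annotation of the same assembly, with 13968 genes. For dm3 no sequence was used and coordinates were not converted. A stricter IDR threshold had been planned by score. As the scale of the score is not stated, the 602 IDR peaks with the highest signal were used in its place, and 598 of them are also among the 602 with the highest score.

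Replicate agreement was the share of IDR peaks that overlapped, by at least 1 bp, one of the N strongest peaks of each replicate, where N is the number of IDR peaks, against 1000 random placements on the same arm. Signal in the replicates was compared across IDR peaks with Spearman's rho and Pearson's r on log2 signal, taking the candidate with the nearest summit, with 100000 permutations and 2000 bootstrap draws. Arms were tested with exact binomial tests against their sequenced length. Summits were placed in the order promoter (within 1 kb of a TSS), 5' UTR, 3' UTR, coding exon, intron and intergenic. Words were searched on both strands within 100 bp of the summit and compared with a window centred 1 kb to one side, the side drawn per peak with a fixed seed, by exact McNemar tests. Dinucleotide-preserving shuffles of the same windows (1000) gave a further control. Gene lists were tested with two-sided Fisher's exact tests of genes with an IDR summit within 1 kb of a TSS. All adjusted p are Benjamini-Hochberg values over the family named beside them, with a threshold of 0.05. Intervals on shares are Wilson 95% intervals, and those on odds ratios of lists are normal approximations on the log scale. Tests were two-sided except those against random placement. Odds ratios of promoters with a word are Mantel-Haenszel values over 10 groups of GC content, each divided by the number of TSSs.

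The genes named in the text follow a rule set before the data were examined: the nearest genes of the 25 IDR peaks of highest signal, the 5 GATA genes, the 4 members of each list with the highest signal at a TSS, and the 5 most extreme replicate ratios on each side. A gene that this rule selects is not reported here. The 21 lists were also set then, and 19 symbols that did not match the annotation exactly were dropped. Other overlaps, windows, words, distances, backgrounds, the dm3 lists, the 602 strongest peaks and the top peaks of each replicate alone were tried as alternatives. Alternatives used 200 placements and 10000 correlation draws, and class shares for random places 100 placements. On dm3 peaks were placed within the span of the pooled candidates of each chromosome. A first test of binding at the GATAd locus, the number of segment candidates among the 1205 strongest of replicate 3, gave 5 and could not tell the explanations apart; it was replaced after that result was seen by the share near the gene. The sides of the flanks kept the first draw made, and their effect is given from 1000 further draws and from the opposite sides, which were added later. The list test was tested on simulated data with 14000 genes, where a list of 33 genes drawn as bound with 3.2 times the weight of other genes was called in 55 of 100 runs and 3 of 2000 unplanted lists were called. The simulation drew each bound gene without regard to its neighbours and used lists of 33 genes only. Its rate of false calls leaves out shared peaks and need not hold for larger lists. Software was Python 3.11.15 with NumPy, SciPy, pandas and matplotlib at versions 2.4.6, 1.17.1, 2.3.3 and 3.10.9.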

Results

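The data set describes where the GATA family transcription factor GATAd was found on the genome of whole Drosophila melanogaster larvae at the wandering stage of the last instar, the stage at which larvae leave the food before pupating. The larvae carried a transgene that makes GATAd fused at its C terminus to green fluorescent protein, and chromatin was precipitated with an antibody against that tag. There is 1 group, GATAd-GFP larvae, with 2 biological replicates that the labels number 2 and 3, males and females pooled. No other genotype, tissue or stage was compared, so the question is where peaks were called, how alike both replicates were, and which genes and sequences lie at the peaks. The measurements are 8 peak lists, and the read depth behind them is unknown.

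On the dm6 genome build the authors' list of peaks that passed the irreproducible discovery rate (IDR, a measure of agreement in rank between replicates) held 1205 peaks. Their signal, the authors' value per peak, ran from 43.9 to 547 with a median of 65.2. These peaks were exactly the 1205 strongest of the 30000 candidates called on the pooled replicates. Being listed therefore does not show that a single peak agreed between replicates. Most were 384 bp wide, and 52 were narrower, down to 96 bp. Each peak has a signal in the pooled list and at most 1 matched value per replicate, so no standard deviation is given for single peaks.

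The strongest peaks lay mostly at promoters. Of the 25 highest, 18 had a summit within 1 kb of a protein-coding transcription start site (TSS), 9 held a WGATAR site (the word GATA factors are known to bind) within 100 bp, and 25 stood among the 1205 strongest peaks of both replicates. The highest signal, 547, was on 3L from 19590467 to 19590765, in intergenic sequence 99 bp from a TSS of CG14100. Ugalt, a UDP-galactose transporter, had a peak of signal 448 on X from 2703751 to 2704043, in intergenic sequence 46 bp from a TSS. Scrawny (scny), a ubiquitin protease, had a peak of 437 in an intron on 3L from 5770879 to 5771124. CG1888 followed with 392 in a 5' UTR on 2R from 9547070 to 9547317. Tcs5 had 371 in intergenic sequence on 3L from 5139360 to 5139625.

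Peaks at 4 mitochondrial ribosomal protein genes were among the highest 25. The mitochondrial ribosomal protein genes mRpL41 (2R, 15217621 to 15217889) and mRpS10 (3R, 15229407 to 15229658) had signals of 344 and 331, in intergenic sequence 127 bp and 128 bp from a TSS. The mRpL23 peak, of signal 249, lay in its 5' UTR on 3L from 2373473 to 2373674. A peak of signal 259 on 2L from 13835354 to 13835554 lay in intergenic sequence 126 bp from a TSS of CenG1A and 366 bp from one of mRpS23. PNPase, the mitochondrial polynucleotide phosphorylase, had a peak of 289 in its 5' UTR on 3R from 31404550 to 31404752.

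Further promoter peaks of the highest 25 were at Lk6, GstE13, LPCAT, CG8320, Chro, ph-p, CG3552 and Trp1. Lk6, a protein kinase gene, had a signal of 308 in an intron on 3R from 11760959 to 11761137. The glutathione transferase gene GstE13 had 303 in its 5' UTR on 2R from 9122097 to 9122322, and LPCAT, a lysophosphatidylcholine acyltransferase gene, had 281 in an intron on X from 9579173 to 9579394. CG8320 had 279 in an intron on 2R from 15992393 to 15992629. Chro, which encodes the chromosomal protein Chromator, had 275 in its 5' UTR on 3L from 22878784 to 22878972, and ph-p, a Polycomb group gene, had 265 in an intron on X from 2137239 to 2137417. CG3552 had 247 in an intron on 3L from 9457688 to 9457861, and Trp1, a protein translocation gene, had 245 in an intron on 2L from 10010146 to 10010317.

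The other 7 of the highest 25 lay over 1 kb from any protein-coding TSS. An intron of CG11050 held the 2nd strongest peak, of signal 492, on 2L from 6612570 to 6612856. An intron of CG32486 held a peak of 362 on 3L from 3060672 to 3060926, whose nearest TSS, 5715 bp away, is that of CG16753. Introns of CG32772 (X, 4910253 to 4910475) and norpA (X, 4324889 to 4325103), the phospholipase C of phototransduction, held peaks of 308 and 280.0. A peak of 258 on 2L from 480963 to 481149 lay in an intron of ush, which encodes a Friend of GATA cofactor, while the nearest TSS was that of cbt at 1352 bp. Intergenic peaks of 282 (2R, 13035225 to 13035419) and 272 (3R, 29214375 to 29214522) lay 11935 bp from CG13323 and 5735 bp from eEF1gamma.

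None of the 5 GATA genes had an IDR peak within 5 kb. GATAd itself (2L, 10333734 to 10339185), whose locus is also carried by the transgene, lay 132703 bp from the nearest IDR summit and had 0 pooled candidates. Replicate 2 had 0 candidates within 5 kb of GATAd and replicate 3 had 8, the strongest ranking 1323 in its list. Over the 240 kb from 10200001 to 10440000 that hold GATAd, replicate 2 had 9 candidates and replicate 3 had 105, where the genome mean gives 53.9. The other 4 genes had weaker candidates in the pooled list, with best signals of 30.4 at pnr, 24.1 at GATAe, 22.5 at grn and 17.0 at srp, all below the weakest IDR peak.

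**Figure D1:**
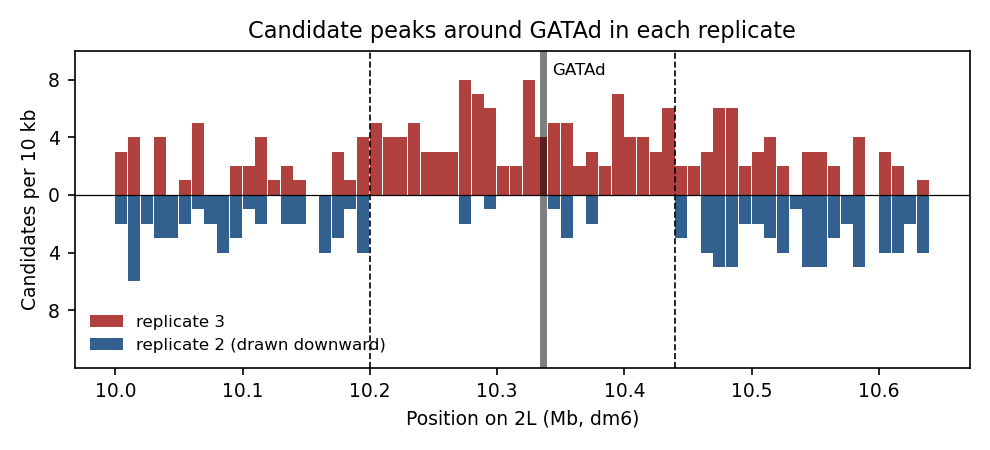
Candidate peaks per 10 kb around GATAd on 2L (Mb, dm6), with replicate 3 drawn upward and replicate 2 downward; dashed lines mark the 240 kb segment and the grey bar GATAd. Within the segment replicate 3 has 105 candidates and replicate 2 has 9.

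The strongest peaks of the replicates overlapped in part. Of the 1205 IDR peaks, 655 (54.4%, Wilson 95% interval 51.5 to 57.2) overlapped one of the 1205 strongest peaks of replicate 2 and one of the 1205 strongest of replicate 3 by at least 1 bp. Random placement of the peaks on their own arms gave 0.350% on average and at most 1.16% (one-sided permutation p = 0.001, the smallest that 1000 placements can give). The top of replicate 2 covered 929 of the IDR peaks (77.1%) and that of replicate 3 covered 865 (71.8%), both counts including the shared peaks, while 66 peaks were in the top of neither. Among the 302 strongest IDR peaks, of signal 88.3 and above, 98.3% were in the top of both, against 77.7%, 35.9% and 5.32% in the next 3 groups of 301. The IDR list and these groups were drawn from the pooled ranking of the same libraries, so the overlap and its fall across groups are not independent of it.

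The signal in replicate 2 and replicate 3 rose together across the 1168 IDR peaks that had an overlapping candidate in both. Spearman's rho was 0.395 (bootstrap 95% interval 0.344 to 0.445) and Pearson's r on log2 signal was 0.505 (0.447 to 0.554), each with a permutation p of 1e-05, the smallest that 100000 draws can give. The relation was across peaks, which are not independent replicates. Among the 594 of the 602 strongest peaks that had both values rho was 0.355 (permutation p = 1e-04, the smallest that 10000 draws can give). Among the 574 weaker peaks with both values rho was -0.526 (permutation p = 1e-05), and a peak enters that set only if its pooled signal is within a narrow range. For 29 IDR peaks replicate 2 had no overlapping candidate, and for 8 replicate 3 had none.

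The ratio between replicates varied across peaks, and the extremes of that spread are named here. The log2 ratio of replicate 3 to replicate 2 had a median of -0.20 and an SD of 0.75 over peaks, and 11 peaks lay more than 4-fold from that median. The lists need not share a scale, so single ratios are given relative to the median. Only the 1168 peaks with a candidate in both replicates have a ratio, and the ranking covers these alone. The 29 peaks without a candidate in replicate 2 and the 8 without one in replicate 3 may be more extreme. The Vha100-2 peak, with 49.4 in replicate 3, is one of the 29. Replicate 2 candidates end at a signal of 9.56 and those of replicate 3 at 6.42, close to the weaker value of several named peaks. The most extreme peaks toward replicate 3 were another ph-p peak (X, 2137729 to 2138112), then CHES-1-like (X, 7696951 to 7697334; 2.57), tst (3R, 23772798 to 23773181; 2.49), PIG-U (2L, 8514809 to 8515192; 2.33) and Btk (2L, 8277598 to 8277981; 2.28), each within 1 kb of a TSS. Toward replicate 2 they were wnd, a stress kinase gene (3L, 19632912 to 19633295; -2.75), the actin gene Act5C (X, 5900026 to 5900409; -2.32), an intron of dy (X, 11776235 to 11776618; -2.22), an intron of the insulin receptor gene InR (3R, 21613309 to 21613692; -2.18) and a site 2719 bp from CG6168 (3L, 11318808 to 11319191; -2.07). With 1 library per replicate, these ratios have no test.

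**Figure D2:**
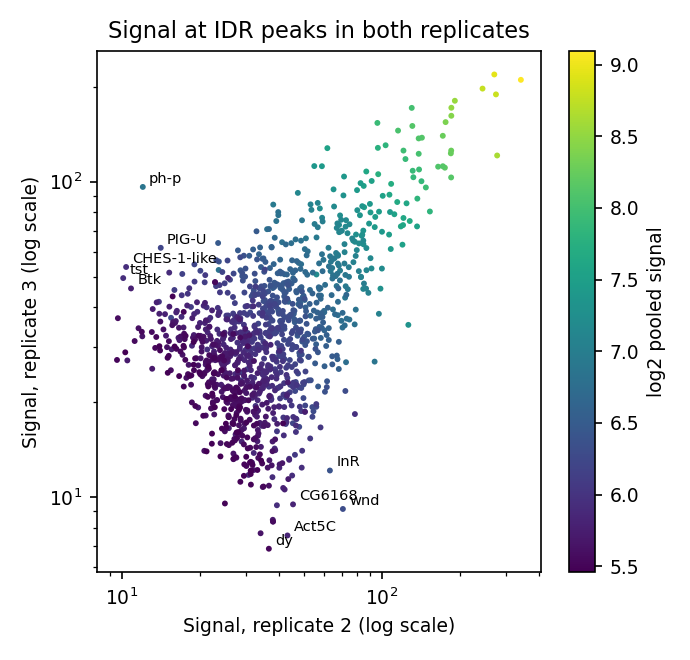
Signal in replicate 2 (x, log scale) and replicate 3 (y, log scale) of each IDR peak with a candidate in both, coloured by log2 pooled signal. The 5 most extreme ratios on each side are named by the nearest gene. Over all 1168 peaks rho is 0.395.

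By chromosome arm, 3R held 301 IDR peaks, 3L 243, X 230, 2L 222, 2R 205 and the small chromosome 4 held 4. The X held 19.1% of the peaks and 17.6% of the sequenced length (exact binomial test, adjusted p = 0.346), and chromosome 4 held 0.332% against 0.996% (adjusted p = 0.0793). No arm passed the threshold against arm length, with adjustment by Benjamini-Hochberg over 6 arms, and none had an unadjusted exact p under 0.05 except chromosome 4 (p = 0.0132). Against the 28795 pooled candidates outside the IDR list 2 arms passed the exact binomial test: the X, which held 14.5% of those candidates (adjusted p = 8.25e-05), and chromosome 4, which held 1.62% (adjusted p = 0.000149). The 1205 strongest peaks of replicate 3 placed 20.7% on 2L (exact binomial adjusted p = 0.0153), and chromosome 4 passed in the top of either replicate.

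IDR peaks lay at promoters. Of the 1205 summits, 841 (69.8%, Wilson 95% interval 67.1 to 72.3) were within 1 kb of a protein-coding TSS, against 20.3% on average and at most 24.5% for summits placed at random on the same arm (permutation p = 0.001, the smallest that 1000 placements can give). Candidates outside the IDR list lay there in 22.9% of cases (Fisher's exact test, odds ratio 7.76, p = 7.58e-248). Within 250 bp of a TSS the share was 54.5% against 6.24% at random. Of the remaining summits, 250 (20.7%) were in introns, 103 (8.55%) between genes, 6 in 3' UTRs, 3 in coding exons and 2 in 5' UTRs. Random placement gave 36.5% in introns, 28.1% between genes and 10.3% in coding exons. The promoter share was 74.5% among the 302 strongest peaks and 61.8% among the 301 weakest.

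**Figure D3:**
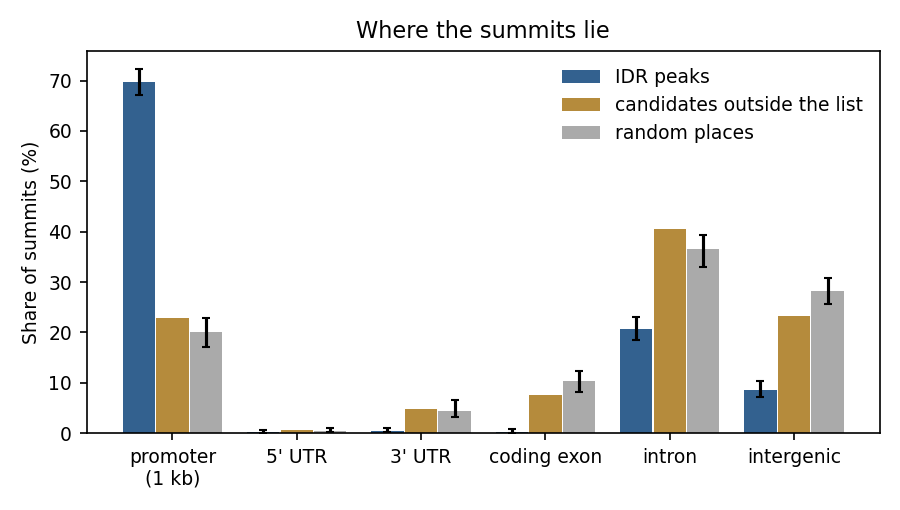
Share of summits (%) in each annotation class for IDR peaks, for candidates outside the list and for random places; bars on IDR peaks are Wilson 95% intervals and bars on random places the range of 100 placements. The promoter class holds 69.8% of IDR peaks, 22.9% of other candidates and 20.1% of random places.

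The GATA word was more frequent at IDR summits than nearby. WGATAR lay within 100 bp of 497 summits (41.2%, Wilson 95% interval 38.5 to 44.0) and in 382 windows (31.7%) of the same width 1 kb to one side (exact McNemar test, p = 8.3e-07). Candidates outside the IDR list held it in 31.3% of cases (Fisher's exact test, p = 1.26e-12). The shares were 40.9% at promoter peaks and 42.0% at the 364 peaks farther from a TSS. Of the single words, TGATAA was at 21.8% of summits and 13.5% of flanks (exact McNemar p = 9.99e-08), while AGATAA was at 13.2% and 11.5% (p = 0.207). Summit windows were richer in A and T, with a GC content of 36.9% against 43.5% in the flanks and 41.0% at candidates outside the IDR list. The control word CCWGG was at 12.1% of summits and 20.5% of those candidates (Fisher's exact test, p = 9.65e-14). Neither comparison is therefore free of base composition. Dinucleotide-shuffled copies of the summit windows held WGATAR in 39.5% of cases (35.4 to 45.1 over 1000 shuffles, two-sided permutation p = 0.234), so the call did not hold against that control, while the core word GATA was at 79.7% of summits and 75.6% of shuffled windows (permutation p = 0.002), a word that DRE also contains.

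No trend of WGATAR with peak strength was detected. The share was 42.7% among the 302 strongest peaks and 41.9%, 41.2% and 39.2% in the next 3 groups of 301. Spearman's rho between signal and the presence of the word was 0.0234 across the 1205 peaks, which are not independent replicates (permutation p = 0.419).

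Among other words, the DNA replication-related element (DRE, TATCGATA), a core promoter word of housekeeping genes, stood out. It lay at 70 summits (5.81%) and 9 flanks (0.747%; exact McNemar test, adjusted p = 1.41e-12 over 9 words), and at 0.288% of shuffled windows. Of those 70 peaks 68 were within 1 kb of a TSS, where the share was 8.09%, and 2 were elsewhere. None of the highest 25 peaks held DRE, but its share was 5.96% among the 302 strongest peaks. In the next 3 groups of 301 it was 5.65%, 4.98% and 6.64%. The control word CCWGG was less frequent at summits (12.1%) than in flanks (27.4%, exact McNemar adjusted p = 2.38e-20), and its shuffled share was 12.8%. Motif 1, another core promoter word, lay at 15 summits and 3 flanks (exact McNemar adjusted p = 0.0226), CAGCTG at 158 and 121 (0.0407) and the AP-1 site at 31 and 15 (0.0407). These 3 calls depended on which side the flank was taken from, and with sides drawn again 1000 times they passed in 575, 258 and 90 draws, while DRE, CCWGG and WGATAR passed in 1000. GAGAG, the GAGA factor word, was at 25.2% of summits and 24.4% of flanks (exact McNemar adjusted p = 0.753), but passed with windows of 200 bp (adjusted p = 0.0157) and was at 20.7% of candidates outside the list (Fisher's exact test, p = 0.000222). Against shuffled windows, a control added for these words after the data were seen, GAGAG (14.1%), CAGCTG (3.31%) and motif 1 (0.0156%) passed along with DRE (permutation adjusted p = 0.0045 each), and the AP-1 site did not (adjusted p = 0.101). Against flanks, CACGTG, the Zelda word and the control GTACGT did not pass either, with exact McNemar adjusted p of 0.795, 0.227 and 0.293, though the Zelda word passed as lower at summits with windows of 200 bp (-1.33 percentage points, adjusted p = 0.044).

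**Figure D4:**
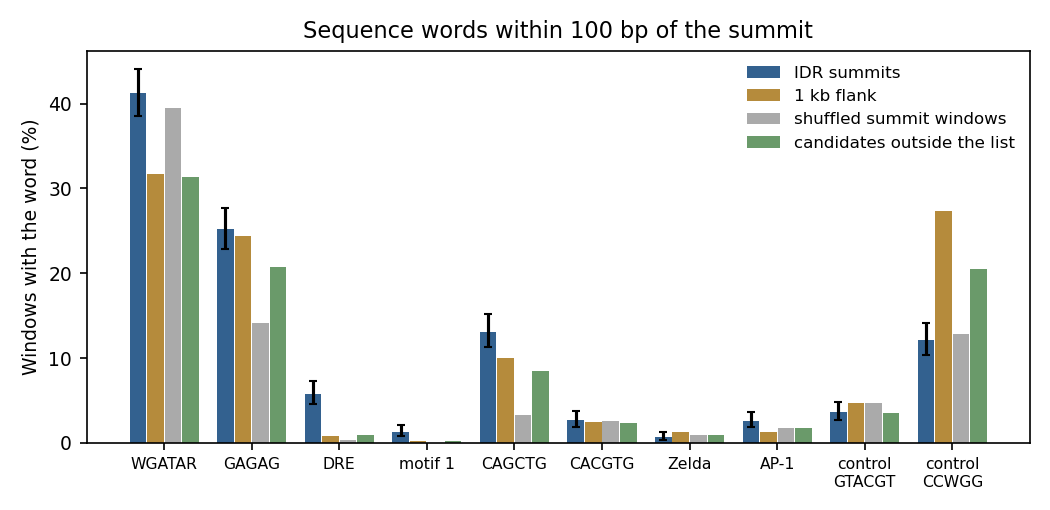
Share of windows (%) holding each word within 100 bp of IDR summits (bars are Wilson 95% intervals), in the 1 kb flank, in shuffled summit windows and at candidates outside the list. WGATAR is at 41.2% of summits, 31.7% of flanks and 39.5% of shuffled windows.

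Genes of the cytoplasmic ribosome were near IDR peaks more often than other genes, and cuticle and barrier genes less often. An IDR summit lay within 1 kb of a TSS of 1225 of 13968 protein-coding genes (8.77%). Of 93 cytoplasmic ribosomal protein genes 21 (22.6%) had one (Fisher's exact test, odds ratio 3.07, 95% interval 1.88 to 5.01, adjusted p = 0.000447 over 21 lists), among them RpL34b (signal 138), RpL32 (131) and RpS27 (123). Of 130 tracheal and epidermal barrier genes, which include the cuticle protein families, 0 had one (exact adjusted p = 0.000264). Both calls ended with the 602 strongest peaks alone, where 10.8% of ribosomal genes and 4.89% of other genes had a peak (odds ratio 2.34, 95% interval 1.21 to 4.53, exact adjusted p = 0.141), and 0 barrier genes and 4.98% of other genes did (exact adjusted p = 0.0673). Fewer genes have a peak in that smaller set, so the tests have less power there. The barrier call also ended with the top of replicate 2 alone, where 2.31% of barrier genes and 8.02% of other genes had a peak (odds ratio 0.271, 95% interval 0.0861 to 0.852, exact adjusted p = 0.093). Neighbouring genes can share a peak, so members of a gene cluster are not independent.

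Mitochondrial ribosomal protein genes had a peak in 12 of 73 cases (16.4%, exact adjusted p = 0.143), led by mRpL41, mRpS10, mRpS23 (259) and mRpL23, and the list passed with peaks within 250 bp (adjusted p = 0.0461) or 5 kb (adjusted p = 0.0331), while with 1 gene per peak its share was 8.96% against 5.79% of other genes (odds ratio 1.60, 95% interval 0.690 to 3.72, adjusted p = 0.748), where the main odds ratio was 2.06 (1.10 to 3.83). Detoxification genes had a peak in 3 of 107 cases (2.80%, exact adjusted p = 0.128), at GstE13, Cyp6u1 (87.1) and GstE14 (83.2), and fell below other genes within 5 kb (3.74%, adjusted p = 0.000919). Fat body genes had a peak in 7 of 27 cases (25.9%, exact adjusted p = 0.051), led by the lipin gene Lpin (137), the ferritin genes Fer1HCH and Fer2LCH, which share a peak of 96.2, and InR (94.3). No Lsp or Fbp gene of the fat body list was among the 7. That list passed with the top of replicate 2 alone (exact adjusted p = 0.0452) and not with 1 gene per peak (5 of 25 genes, against 5.78% of other genes, adjusted p = 0.0916). Oxidative phosphorylation genes had a peak in 10 of 84 cases (exact adjusted p = 0.628), led by ND-ASHI (84.7), ND-24 (81.1), ND-42 (69.9) and ND-SGDH (68.1), and vacuolar ATPase genes in 5 of 33 (adjusted p = 0.587), led by Vha16-5 (88.2), Vha14-1 (74.7), Vha100-2 (72.4) and Vha13 (45.5).

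Genes of the ecdysone response, the steroid pathway that drives metamorphosis, had a peak in 4 of 29 cases (13.8%, exact adjusted p = 0.628): Eip63F-1, the receptor subunit gene usp (55.2), Hr3 (44.3) and Eip75B (44.2). Stress genes had a peak in 5 of 35 cases (exact adjusted p = 0.587), led by Hsp27 (189), Atf3 (93.5), Keap1 (53.8) and Hsp110 (49.1), and passed with the top of replicate 3 alone (28.6%, adjusted p = 0.00713) but not of replicate 2 alone (8.57%, adjusted p = 0.934). Gut stem cell and regional fate genes had 3 of 29 (exact adjusted p = 0.947), namely fkh (161), Krn (93.7) and lab (84.7), and midgut digestive enzymes 1 of 43 (adjusted p = 0.587), Mal-A5 (93.9). Cell cycle genes had 4 of 33 (exact adjusted p = 0.741), aurA (86.8), Mcm5 (80.2), fzr (50.2) and Mcm2 (46.1).

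The remaining lists did not pass. Immune genes had 2 of 36 (exact adjusted p = 0.947), cact (74.3) and Myd88 (48.5), and heart and muscle genes 2 of 25 (adjusted p = 1), Msp300 (114) and tin (49.2). Neuronal genes had 1 of 18 (elav, 76.1; exact adjusted p = 1), salivary glue genes 1 of 15 (fkh; adjusted p = 1), disc patterning genes 1 of 31 (dac, 53.3; adjusted p = 0.741) and Hox genes 1 of 8 (lab; adjusted p = 0.741). Blood cell genes had 0 of 21 (exact adjusted p = 0.587), Notch targets 0 of 17 (adjusted p = 0.687) and the GATA genes 0 of 5 (adjusted p = 1). In the salivary glue list fkh is a regulator rather than a glue gene, and it was also counted in the gut fate list. No Sgs gene of that list had a peak. Lists of this size give little power, and a p above the threshold does not show that a list matches other genes.

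**Figure D5:**
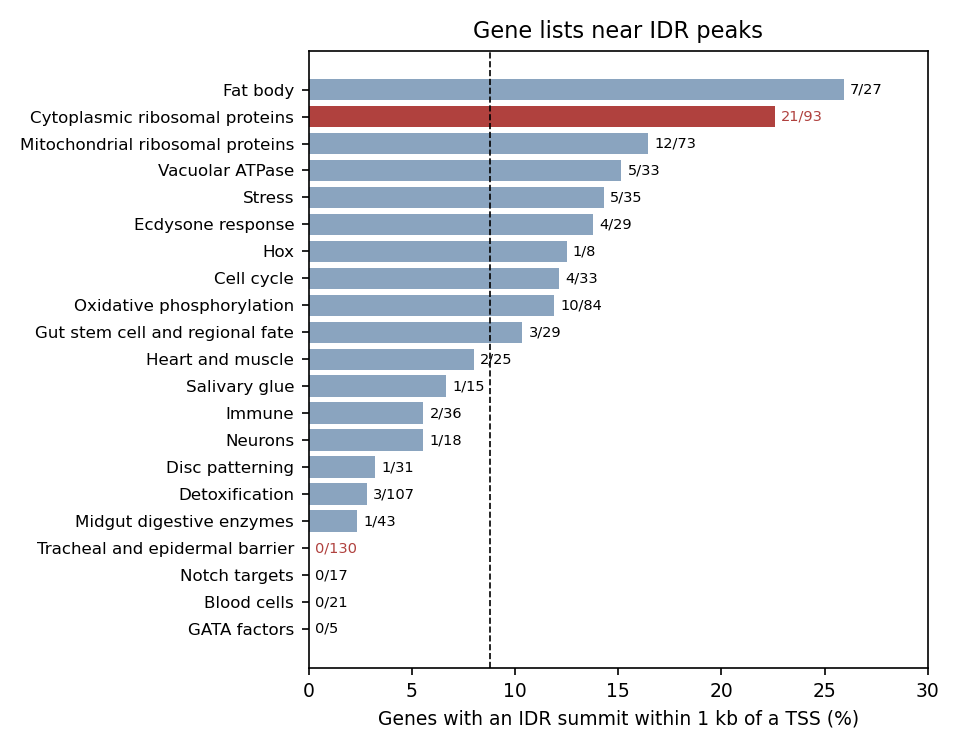
Share of genes (%) in each fixed list with an IDR summit within 1 kb of a TSS, with counts; red marks an adjusted p under 0.05 and the dashed line all protein-coding genes (8.77%). Ribosomal protein genes reach 22.6% and barrier genes 0.

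On the older dm3 build the IDR list held 1188 peaks, with signals from 37.1 to 546 and a median of 56.7. By arm it held 277 on 3R, 246 on X, 234 on 3L, 226 on 2L, 198 on 2R, 3 on chromosome 4 and 4 on sequence outside these arms, where the dm6 list held 0. Among the pooled candidates 385 of 30000 lay outside the arms on dm3 and 0 on dm6. Coordinates were not converted between builds, so single peaks were not matched.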

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

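The tests of the segment around GATAd, the shuffle tests of TGATAA and core GATA and the odds ratios of TGATAA and CACGTG were chosen after their result was seen.

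The single-replicate candidate lists were used in the report mainly at IDR peaks, and away from these peaks they hold a block of unequal candidates around GATAd itself. Over the 240 kb from 10200001 to 10440000 on 2L, which hold 87 protein-coding genes, replicate 3 had 105 candidates (Poisson 95% interval 85.9 to 127) and replicate 2 had 9 (4.12 to 17.1), and the edges of the segment were fitted to these same counts. Binding at the GATAd locus would place the candidates near the gene, and 7.62% of those of replicate 3 lay within 5 kb of it, in 6.44% of the segment's length. Poor mappability would lower both replicates, and replicate 3 had 1.95 times the candidates of the genome mean. The segment was picked by its excess of replicate 3, which can raise that number, so it does not decide about mappability. A difference between libraries in the number of DNA copies of this region remains a candidate explanation that these counts cannot decide: 100% of the 23 bins of 10 kb outside GATAd held more candidates of replicate 3, but the edges were fitted to these bins, and reads that would show copy number were not analysed here.

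WGATAR stood at 41.2% of IDR summits and 31.7% of flanks. Shuffled copies that keep the dinucleotides of each summit window held it in 39.5% of cases, and no difference was detected (two-sided permutation p = 0.234). The copies also keep the dinucleotides of any GATA site, so whether base composition accounts for the share stays open. TGATAA and the core word GATA, at 79.7% of summits against 75.6% when shuffled, did exceed them (permutation p = 0.002 for each, the smallest that 1000 shuffles can give). DRE contains GATA and may give part of the rise of that core word. The share of TGATAA was 1.25 times the shuffled share at summits and 1.05 times in flanks, a ratio of 1.19 (bootstrap 95% interval 1.02 to 1.37). TGATAA was singled out by its excess at these same summits, which can raise the ratio. The interval therefore does not decide whether a preference for TGATAA is shared with the flanks. For WGATAR as a whole the ratio was 1.07 (0.987 to 1.17), which leaves it open too. Binding of GATAd at GATA sites stays open as a hypothesis: the central 51 bp held WGATAR at 13.9% of peaks, against a shuffled median of 12.1% (two-sided permutation p = 0.05), and TGATAA at 7.30% against 4.73%. Of the other forms of the word, AGATAA was at 3.98% against 4.15% (permutation p = 0.859), AGATAG at 2.07% against 1.74% (permutation p = 0.45) and TGATAG at 1.08% against 1.91% (permutation p = 0.04).

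IDR peaks lay at promoters in 69.8% of cases. Genes with the DRE word within 100 bp of a TSS had an IDR peak in 12.5% of cases and other genes in 8.44%, with a common odds ratio at equal GC content and number of TSSs of 1.36 (95% interval 1.13 to 1.64). Genes with WGATAR there had an IDR peak in 10.3% of cases and other genes in 7.90%. At equal GC content and number of TSSs the odds ratio was 1.05 (0.929 to 1.19), so no association was detected, while TGATAA gave 1.19 (1.03 to 1.38). A promoter peak may lie up to 1 kb from the TSS, outside the 100 bp searched, so this does not decide whether WGATAR at the peak matters. Signal tied to housekeeping promoters stays a possible explanation that was tested through 1 word only, and 68 of the 841 promoter peaks held DRE. The word CACGTG, which was not one of the control words, gave an odds ratio of 1.30 (0.989 to 1.71). Whether another tagged factor would give the same promoters was not tested, as no such peaks were analysed here.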

How the results depend on the processing

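The controls of flanks on the other side, and of shuffled windows for words other than WGATAR, were added after the data were seen. Of 53 alternative values for the main results, 42 kept their direction and side of the threshold or stayed within 1.5 times a count. A count could be kept while its members changed. With the top of replicate 2 alone, fat body took the place of the barrier list. Against shuffled windows GAGAG passed, while the AP-1 site and CCWGG did not. The overlap shares were compared with random placement of peaks drawn from the same libraries, so their staying past the threshold says little. The 602 strongest peaks, a set fixed by its construction, left 0 gene lists past the threshold where all peaks gave 2, and peaks within 5 kb gave 4. Against candidates outside the list 2 arms passed instead of 0, and with the top of 1 replicate alone 1 to 2 did. The excess of WGATAR over its control, 9.54 percentage points in the main test, was 1.75 points against shuffled windows and 1.74 points for AGATAA alone, and neither passed. Of 9 other words 5 passed in the main test, 2 with windows of 50 bp or the flank on the other side and 1 without promoter peaks, where motif 1 turned to -0.275 points. The cause of these changes was not tested. The top-of-both share, 54.4%, was 29.6% with the 602 strongest of each replicate and 80.3% with a top 2 times as long, and 71.8 to 77.1% where only 1 replicate was required, and with the top of 1 replicate alone 65.5 to 72.9% of peaks were near a TSS, the excess of WGATAR was 8.80 to 9.71 points and 2 to 3 gene lists passed. Of 213 values for single arms, words and lists 187 were counted as unchanged, 12 passed only under the alternative, 13 no longer passed and 1 turned. The 187 include the arm shares on dm3, for which no test was run, so they have no side of the threshold. Depth is unknown, so its effect was not tested.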

Other observations

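The word test was chosen after enriched words had been seen in all peaks, and genes in this part were chosen after their values were seen.

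Some genes held several IDR peaks. Within 1 kb of the gene body, 1437 genes held 1 IDR peak, 157 held 2 and 24 held 3. The gene sbb (2R, 18278198 to 18357296) held 6, with signals from 53.9 to 83.6. The cell adhesion gene kirre, 394 kb long on X, and CHES-1-like, also on X, held 5 each, with highest signals of 134 and 124. The RNA-binding protein gene larp and the kinase gene Raf held 4 each, with highest signals of 182 and 134, as did CG1677 with 98.6. Long genes can hold more peaks by length alone, which was not tested.

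Peaks of replicate 3 lay near several heat shock and stress genes. Among the 1205 strongest peaks of replicate 3, a summit lay within 1 kb of a TSS at Hsp27 (signal 128), Atf3 (38.1), Hsp68 (30.7), hid (29.7), Hsp60A (28.4), puc (28.2), Keap1 (27.7), Hsp110 (26.1), Hsc70-4 (25.7) and Hsp22 (24.7). In the top of replicate 2 there was one at Hsp27 (61.6), Atf3 (45.8) and Keap1 (43.5). These are 10 of 35 stress genes in replicate 3 and 3 in replicate 2, and 5 had an IDR peak. Over all protein-coding genes the share with such a summit was 9.34% in the top of replicate 3 and 7.97% in that of replicate 2. The difference between the replicates was not tested, since each has 1 library.

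Of 1342 windows of 100 kb, 6 stood out for unequal numbers of candidates when ranked against counting error alone, which leaves out the spread between libraries, so no p is given. Away from GATAd they were at 2R from 13900001 (15 in replicate 2 and 44 in replicate 3), chromosome 4 from 100001 (23 and 57), 3L from 1200001 (33 and 7) and 3L from 22500001 (24 and 3). Replicate 3 had more candidates over chromosome 4 as a whole (574 against 334), so that window need not be a local difference. The windows at GATAd had 3 and 48, and 6 and 40.

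A word other than GATA or DRE may mark part of the peaks. The 10 words of 6 bases most enriched over shuffled copies in the 602 IDR peaks of even rank, leaving out words with GATA or part of DRE and words no more frequent than in the flanks, were tested in the 603 of odd rank, and 4 held there against shuffled copies and both flanks. Of these, AAATAT and ATATAT are runs of A and T. ACAGTG lay at 21.2% of odd-rank summits against 7.30% and 8.13% in the flanks (exact McNemar adjusted p = 1.74e-09) and 7.23% when shuffled, and ACACTG at 18.2% against 5.80% and 7.63% (adjusted p = 1.24e-07). ACACTG can be the end of motif 1, which was not left out of the search and lay whole at 15 IDR summits. ACAGTG and the reverse complement of ACACTG overlap, so they need not be separate words. CAGTGC, CACTGA, CAGTGG and CACTGG share their core CAGTG on either strand and did not hold against both flanks (exact McNemar adjusted p of 0.0523 and above). ACAGTG was at 18.7% of promoter peaks and 23.4% of other peaks, so it was not confined to promoters as DRE was. Which protein, if any, these words bind was not tested.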
